A study of Mus musculus with 16 samples.

How the data were processed

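RNA was measured in 16 libraries of the mouse embryonic stem cell line E14Tg2a (strain 129/Ola). In these cells the endogenous CTCF protein carries a degron, a tag that marks it for destruction when auxin is added, and a doxycycline-inducible transgene supplies either wild-type CTCF (WT) or CTCF with 1 of 3 changes in its DNA-binding domain (R342C, K365T or Q418R). Per the labels, all 16 cultures received 500 µM indole-3-acetic acid, an auxin, and 1 µg/ml doxycycline, for which the protocol gives 2 days. One arm stayed in serum medium with leukemia inhibitory factor (LIF), 3 µM CHIR99021 and 1 µM PD0325901, an inhibitor of MEK, and the other was kept for 3 days without these 3 additions, called no LIF here. Each of the 8 combinations of line and medium has 2 libraries. From each culture 500 ng of RNA entered a stranded total RNA protocol with ribosomal RNA depletion, and 150 bp paired reads were sequenced.

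The authors' notes name Trim Galore, STAR and DESeq2 and the genome build mm10, without versions, and state neither the counting tool nor the annotation. The deposited main table holds the authors' normalised counts (a signal scaled by 1 factor per library), with 1 column for each of the 16 libraries and 55291 genes. Its values are whole multiples of 1 step per library, the value of 1 read, which lay between 0.779 and 1.19. Divided by that step, 100% of the values in every library were whole within a tolerance of 0.05, so that read counts could be recovered, 19721363 to 31935381 per library. The second deposited table holds TPM, values scaled for gene length and depth, computed by the authors, with gene lengths that are not stated, and it served as an alternative. No sample was left out, and no library of untreated cells belongs to the series.

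Log2 of the normalised count plus 4 was fitted with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend) in R 4.3.3. The model had 1 mean for each of the 8 groups and 8 residual degrees of freedom, so that the spread was shared across groups of 2. The 17757 genes with a mean normalised count of at least 10 over the 16 libraries were tested, of 37742 with a value above 0 in any library, and p was adjusted by the Benjamini-Hochberg method over these genes, with a threshold of 0.05. The contrasts were no LIF against LIF in each line, each mutant line against WT in each medium, the difference between a mutant's and the WT response (an interaction), and a moderated F test among the 3 mutants in each medium. Because 4 is added before the logarithm, log2 differences of genes with counts near 0 are compressed. For genes with at most 3 recovered reads in a group, a ratio is given instead, with a 95% exact binomial interval or, where both libraries were at 0, against a floor of 3 reads over the 2 libraries. These intervals and floors cover counting error only.

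Genes to be named, 23 gene lists, all contrasts and most alternatives were fixed before the data were examined. Named were Ctcf, 14 key genes for the WT response, and in each contrast the 5 genes with the largest rise and the 5 with the largest fall among those under the threshold with a mean of at least 100, without overlap between the libraries of the 2 groups and leaving out clone names. A few genes that these rules pick are not named. Each list described gives up to 4 of its members under the threshold, by size of change, or the 2 most abundant where none passed. The F tests name the 5 genes with the smallest p and a mean of at least 100. The lists were naive, general, and formative and primed pluripotency; primitive streak and mesoderm; endoderm; neuroectoderm; trophectoderm; the 2-cell-like state; LIF and STAT3 targets; MEK and ERK targets; Wnt targets; the protocadherin alpha, beta and gamma clusters; Hox clusters; imprinted genes; germline genes; p53 targets; CTCF, cohesin and their regulators; unfolded protein and amino acid stress; proliferation; fibroblast and feeder cells; and mitochondrially encoded genes. Of these, 21 had at least 3 tested members and were tested in 13 contrasts with camera and an estimated correlation between genes, 273 tests adjusted together, with camera at a preset correlation of 0.01 and fry as alternatives.

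Gene positions came from GENCODE release M21 (mm10), where 53186 of the 55291 names (96.2%) and 17380 of the 17757 tested genes (97.9%) had 1 position. Median differences from WT were taken in 10 Mb windows with at least 8 genes of mean 100 or more. A window was called shifted when its median over both media lay at least 0.25 from that of all genes and a neighbouring window passed the same bound on the same side. Genes of windows with fewer than 8 genes of that level, as on chromosome 17 from 90 Mb, count as outside. This rule was set after the data were seen. Correlations between mutants were compared with 100 simulated data sets without any effect in the same design, since the mutants share their WT libraries. The spread of each group in these simulations and the covariance with a different WT library for each mutant were chosen after the data were seen.

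Alternatives were pseudocounts of 1 and 16, no filter and a mean of at least 50, upper-quartile scaling, the TPM table with 0.1 added, replicate number as a block, the 8 libraries of 1 medium alone, each library left out in turn, and the recovered reads in edgeR 4.0.16 (quasi-likelihood, TMM factors) and DESeq2 1.42.0. Chosen after the data were seen were a replicate block within each line and a fit to the 14073 genes outside the shifted windows, recentred. On simulated data made from these libraries, with 50 changed genes at each size, limma recovered 6% of 1.5-fold, 40% of 2-fold, 86% of 4-fold and 96% of 8-fold changes in K365T against WT in LIF, with 12 unchanged genes called. For an interaction the shares were 2%, 12%, 58% and 74%, with 3 unchanged genes called. DESeq2 called 37 unchanged genes in K365T against WT in LIF and 17 for the interaction. Simulated shifts were found in 9 of 9 windows and in 0 of the 262 others, and 0 of 20 unchanged lists were called by camera with an estimated correlation. The simulated shifts were not graded by size, so this does not show how many shifts near the bound of the window rule are found. The 0 of 262 holds for the simulated data only.

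Normalised totals were 22395400 to 24870231 per library, and 1 read was worth about 1 normalised count, which limits statements on genes near 0. Replicates differed far more than counting error allows, with chi-square per degree of freedom from 16.8 to 53.9. The SD between replicates on the log2 scale ran from 0.25 (R342C in LIF) to 0.41 (K365T without LIF). The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, which may be technical. Residuals of same-numbered libraries were correlated by over 0.1 in 13 of the 28 pairs of groups, with values from -0.39 to 0.45, and in the 4 pairs of 1 line in both media the values were 0.27 to 0.30. The main model does not pair samples by replicate number, and the replicate block within each line shows what such pairing does to the responses and their differences.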

Results

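Total RNA from mouse embryonic stem cells was sequenced in 16 libraries. The cells had their own CTCF, a zinc finger protein that binds DNA and shapes chromosome loops, marked for degradation, and expressed a transgene with wild-type CTCF (WT) or with the R342C, K365T or Q418R change. Each of the 4 lines was profiled in medium with LIF and 2 inhibitors, which holds cells in the naive pluripotent state, and after 3 days without them, when cells leave that state. There were 2 libraries per line and medium, and 19721363 to 31935381 reads per library could be recovered from the normalised counts. The series asks how the mutations affect this exit. Medium was the main axis of variation, with 76.5% of the variance of log2 values on the first principal component and 6.32% on the second. In WT without LIF, replicate 2 stood apart, with 7.28% of its normalised counts from structural RNAs against 2.46% to 5.45% in the other 15 libraries. Against WT without LIF, each mutant had fewer genes under the threshold with this library left out than with WT replicate 1 left out. The cause of this was not tested. Each genotype is represented by 1 line, so that a difference between genotypes is also a difference between lines.

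Ctcf itself was abundant in every library. In LIF its normalised count was 6956 and 5853 in the 2 WT libraries, 6449 and 6194 in R342C, 6944 and 8585 in K365T, and 8375 and 7369 in Q418R. Without LIF it was 6242 and 5292 in WT, 5589 and 6032 in R342C, 6541 and 6574 in K365T, and 8406 and 6241 in Q418R. No contrast of Ctcf passed the test, and the mutants' log2 differences from WT lay between -0.01 and 0.33. These reads do not separate the endogenous gene from the transgene, and they do not show which mutation a library carries.

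Removal of LIF and the inhibitors in the WT line changed 8665 of 17757 genes at an adjusted p under 0.05, 4235 of them higher and 4430 lower. The largest rises were those of Car4, a carbonic anhydrase (log2 change 9.41 ± 0.28 SE, from 2.01 ± 1.74 to 4023 ± 760 normalised counts, SD, n = 2), Kif1a, a kinesin motor (7.70 ± 0.27), Fam131b, the chemokine gene Cxcl12 (7.18 ± 0.35) and Ccdc194 (7.04 ± 0.38). The largest falls were those of Crxos, a homeobox gene (from 4560 ± 137 to 0.957 ± 1.35), Bhmt (-8.65 ± 0.27) and Dmgdh, neighbours on chromosome 13 that encode enzymes of betaine metabolism, Ly6a, which encodes the surface antigen Sca-1 (-8.60 ± 0.38), and the aldehyde oxidase gene Aox3 (-8.05 ± 0.36). Crxos had 2 recovered reads left in the 2 libraries, a level 4429 times lower (95% exact interval 1226 to 36576). Dmgdh had 3, a level 903 times lower (309 to 4381), and Fam131b rose from 1 read, by 1892 times (339 to 74789). The highest adjusted p among these 10 genes was 1.8e-08.

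Genes of the naive state fell together. Of the 18 members of the naive list 17 fell and 0 rose, and the counts adjusted over the list alone were also 17 and 0. On the log2 scale Nanog (-3.45), Klf4 (-4.66), Esrrb (-2.28), Zfp42 (-2.79) and Tfcp2l1 (-5.13) fell, and Prdm14 (-6.08 ± 0.50), Dppa3 (-5.24 ± 0.55) and Nr5a2 (-5.24 ± 0.25) fell further than most. Of the general pluripotency genes 6 of 15 fell and 2 rose (7 and 3 adjusted over the list alone). The core factors Pou5f1 (-0.66) and Sox2 (-0.95) fell less than 2-fold, Tdgf1 (-2.82) and Gdf3 (-2.19) fell more, and Lin28a (3.54) and Utf1, from 445 ± 21.4 to 7209 ± 664 normalised counts (SD, n = 2), rose. Formative and primed genes moved the other way, with 15 of 18 higher and 0 lower, the same over the list alone. Among them Pou3f1 (4.97 ± 0.41), Foxp1 (3.96 ± 0.28), Lin28b (3.86 ± 0.25), the DNA methyltransferase gene Dnmt3b (3.27) and Otx2 (2.31) rose. Fgf5 rose from 1 recovered read to a mean of 114 ± 99.7 (SD, n = 2), a ratio of 265 with a 95% exact interval of 47.1 to 10503. Camera called 0 of the 273 list tests with an estimated correlation; for naive genes and for formative genes the adjusted p = 0.395 with an estimated correlation, against 1.79e-09 and 2.04e-08 with the preset one and 2.36e-05 and 3.71e-05 by fry.

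**Figure D1:**
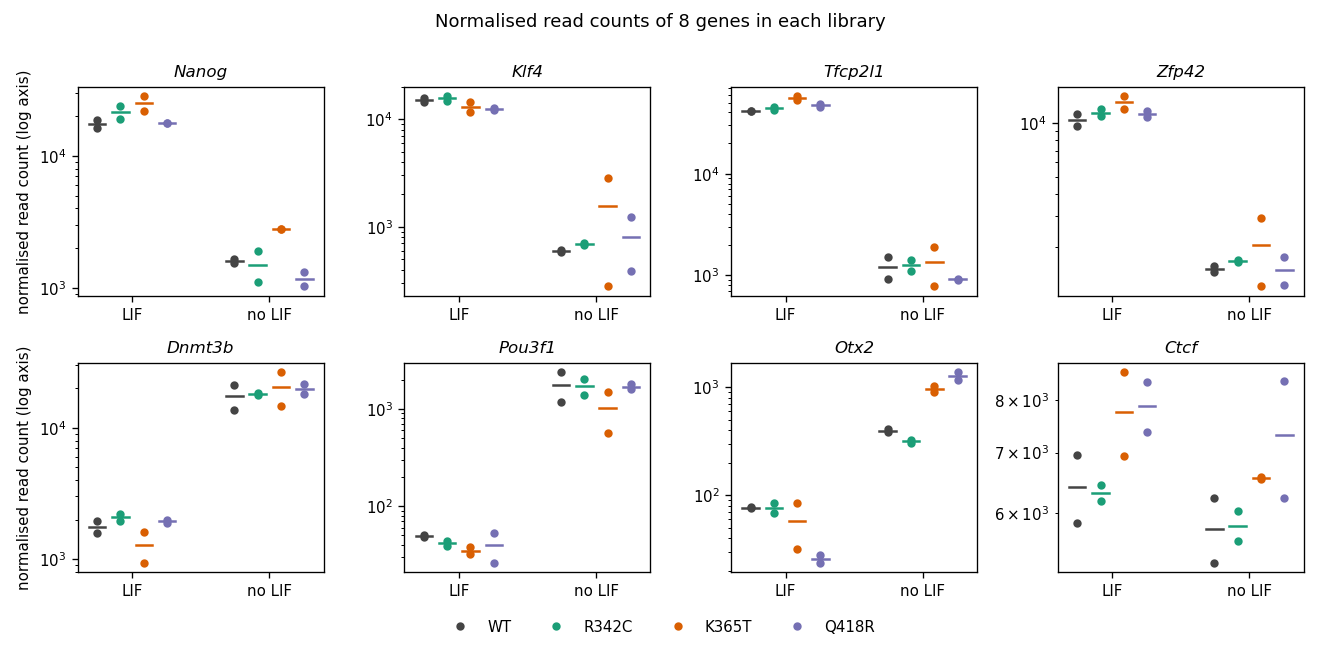
Normalised read counts (log axis) of 8 genes in each of the 16 libraries by medium, with points for libraries, bars for the mean of 2, and colours for the 4 lines. Nanog, Klf4, Tfcp2l1 and Zfp42 lie lower without LIF, Dnmt3b, Pou3f1 and Otx2 lie higher, and Ctcf lies between 5292 and 8585 in all 16 libraries.

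Signalling genes changed in both directions. Of 14 LIF and STAT3 targets 7 fell and 3 rose, the same over the list alone, with falls of Socs3, a feedback inhibitor of STAT3 signalling (-4.04 ± 0.32), and of Pramel7, which went from 609 recovered reads to 0 and so was at least 180-fold lower against the floor of 3 reads over both libraries. Of 18 MEK and ERK targets 9 rose and 2 fell, the same over the list alone. Among these the feedback inhibitors Dusp4 (4.58 ± 0.36), Spry4 (4.49 ± 0.45) and Dusp6 (2.85 ± 0.22) rose. The 14 Wnt targets were split, 5 higher and 6 lower (6 and 6 over the list alone), and Cdx1 (-7.96 ± 0.57), Sp5 (-6.23 ± 0.72), Dkk1 (-5.14 ± 0.50) and Apcdd1 (-2.65 ± 0.14) were the largest changes. For MEK and ERK targets the adjusted p = 0.572 with an estimated correlation.

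Lineage markers were mixed. Their counts are to be read against all 17757 genes, of which 4235 rose and 4430 fell. In the primitive streak and mesoderm list 5 of 15 genes rose and 5 fell, the same over the list alone, with Kdr (-3.42) and Gsc (from 184 to 7.84 normalised counts) lower, Foxf1 (2.47) and Hand1 (2.04) higher, and T without a call (-0.06, adjusted p = 0.958). In the endoderm list 9 of 15 rose and 3 fell (9 and 4 over the list alone), where Lamb1 (4.68), the adaptor gene Dab2 (2.82) and Cubn (2.71) rose and Lama1 (-4.66) and Gata6 (-1.09) fell. Of 11 neuroectoderm genes 6 rose and 1 fell, the same over the list alone, with Sox11 (5.47), Pax6 (3.31), Map2 (1.84) and Sox1 (0.97) higher. The trophectoderm list had 5 of 11 higher and 5 lower, the same over the list alone, including Fgfr2 (4.23), Krt18 (2.24), Tead4 (-3.30) and Tfap2a (-2.62). Of 10 genes of fibroblasts and feeder cells 8 rose and 1 fell, the same over the list alone, with Tagln (4.87), Acta2 (4.48) and Thy1 (3.94) higher; Dcn, a marker of fibroblasts, went from 0 to 185 recovered reads and was at least 74.5-fold higher. For the last list and for neuroectoderm the preset-correlation calls were lost, with adjusted p = 0.44 and adjusted p = 0.439 with an estimated correlation. The calls of Sox1 and Gata6 each ended with at least 1 WT library left out, with adjusted p up to 0.107.

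Of 28 Hox genes 24 fell and 0 rose (24 and 1 over the list alone), from low levels. Hoxc4 fell by 4.69, Hoxb13 went from 265 reads to 1 (232 times lower, 41.3 to 9205), Hoxc12 from 309 to 3 (90.2 times, 30.6 to 440) and Hoxc11 from 181 to 2 (79.3 times, 21.6 to 660). Imprinted genes, which are expressed from 1 parental allele, rose in 19 of 29 cases and fell in 1 (19 and 4 over the list alone), led by H19 (4.38 ± 0.41), Peg10 (4.27 ± 0.38), Nnat (3.76 ± 0.45) and Igf2 (3.56 ± 0.75). For both lists the adjusted p = 0.395 with an estimated correlation, against 2.25e-08 and 6.34e-05 with the preset one.

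The other lists moved less or in both directions. Of all 17757 genes 4235 rose and 4430 fell, so that similar shares do not set a list apart. Germline genes had 7 of 19 higher and 4 lower (8 and 4 over the list alone), with Rhox5 (2.64) and Tdrd1 (2.63) higher and Dazl (-2.76) and Hormad1 (-2.33) lower. Of 9 genes of the 2-cell-like state 2 rose, Zscan4a (1.02) and Zscan4e (0.91), paralogs that share sequence, and 0 of the 9 passed over the list alone. Of 14 protocadherin gamma genes 1 rose and 5 fell, the same over the list alone, with Pcdhgb7 (-1.27), Pcdhga11 (-1.24), Pcdhga1 (-1.05) and Pcdhga12 (-0.95) lower. In the alpha cluster Pcdhac2 (mean 17.8) was the 1 gene that reached the filter, and in the beta cluster 0 genes did, so neither was tested. The CTCF and cohesin list had 7 of 21 higher and 3 lower, the same over the list alone: Rad21l (2.83) and Ctcfl (2.65), germline relatives of cohesin and CTCF genes, Stag2 (1.37) and Hdac8 (0.86) rose. Of 18 p53 targets 3 rose and 4 fell, of 18 stress genes 3 rose and 7 fell, both the same over the list alone, and of 18 proliferation genes 1 rose and 2 fell (1 and 1 over the list alone). Among these Cdkn1a (-1.81), Asns (-2.23), Rrm2 (-1.60) and Cdk1 (-0.34) fell and Pmaip1 (1.87) and Slc7a11 (2.20) rose. Of 13 mitochondrially encoded genes 3 fell and 0 rose, the same over the list alone: mt-Nd1 (-0.78), mt-Nd2 (-0.64) and mt-Cytb (-0.46). The calls of Zscan4a, Zscan4e, Pcdhgb7, Pcdhga11, Pcdhga1, Pcdhga12, Hdac8, Cdk1 and mt-Cytb ended with at least 1 WT library left out, with adjusted p up to 0.446 (Pcdhga1 without replicate 1 of WT without LIF).

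The mutant lines responded to the medium on a similar scale. In R342C 8387 genes changed (4140 higher, 4247 lower), in K365T 7934 (3843 and 4091) and in Q418R 8252 (4076 and 4176). The balance depended on the scaling: with TPM 60.4% of the Q418R calls were higher against 49.4%, and with upper-quartile scaling 55.8% of the K365T calls against 48.4%. Car4 was among the largest rises in each, with log2 changes of 9.04 ± 0.28 in R342C and 8.34 ± 0.28 in K365T, and from 1 recovered read in Q418R, by 3691 times (662 to 145841). Cxcl12 rose in each as well, from 2 recovered reads in R342C by 917 times (253 to 7578) and from 1 in K365T by 2036 times (364.99 to 80456). Fndc3c1 rose by 7.57 in R342C and 6.93 in K365T, Lefty1, an inhibitor of Nodal signalling, by 7.50 in R342C and 7.47 in Q418R, and Car14 by 7.17 in K365T and 7.14 in Q418R. Other large rises were Kif1a in R342C (7.81) and the ephrin receptor gene Epha1 in K365T (6.79). Ly6a fell in all 3 (-8.45 in R342C, -7.67 in K365T and -7.45 in Q418R), as did Bhmt (-8.46 in R342C, -8.08 in K365T and from 2502 reads to 1 in Q418R). Crxos (-9.04 in R342C, -8.22 in Q418R), Aox3 (-7.42 and -7.99) and Dmgdh (-7.68 in R342C) also fell. In K365T Aspa (-7.19) and Serpinb6c (-7.03) fell and Mgat4c went from 1897 reads to 1, and in Q418R the channel gene Trpm1 fell by 7.86. Across genes, which are not independent replicates, the response correlated with that of WT at r = 0.965 in R342C, 0.913 in K365T and 0.929 in Q418R, with slopes of 0.955, 0.861 and 0.913. Of the genes called in both, 0 changed in opposite directions in R342C, 23 in K365T and 9 in Q418R.

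In LIF the R342C line differed from WT in few genes, 59 higher and 15 lower. The imprinted zinc finger gene Peg3 (chromosome 7, 6703892 to 6730431, mm10) fell by 2.94 ± 0.25, from 2557 ± 198 in WT to 339 ± 119 (SD, n = 2; adjusted p = 9.98e-05). On the X chromosome Efhc2 (-3.07 ± 0.31), Xlr3c (-2.76 ± 0.37) and Xlr3b (-1.57 ± 0.31) were lower, the last 2 from a family of close paralogs, and Ank2, an ankyrin gene, fell by 1.58. Higher were Rassf4 (1.64 ± 0.29), the imprinted Sgce (1.59 ± 0.24), and 3 genes of distal chromosome 17, Clip4 (from 84.2 ± 27.6 to 240.3 ± 40.5 normalised counts), Ston1 (1.29 ± 0.17) and Cdc42ep3 (1.26 ± 0.20). Of the 59 higher genes 49 lay on chromosome 17 after position 71768473, where no gene was lower. Peg3 and Sgce were the only 2 of 29 imprinted genes called, and 1 higher and 4 lower passed over the list alone; the list's median of -0.06 turned to 0.07 with TPM, and for its preset-correlation call the adjusted p = 0.551 with an estimated correlation. Without 1 library the count was 30 (R342C replicate 2) to 48 (R342C replicate 1) in place of 74, with 40 and 46 without WT replicate 1 and 2, and the calls of Rassf4, Sgce, Clip4, Cdc42ep3, Ank2 and Xlr3b ended in at least 1 of these 4 fits. With genes outside the shifted windows alone 16 were called, 50.0% of them higher, and by DESeq2 149. The genes outside still included those of chromosome 17 from 90 Mb, where the median difference was 0.98.

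K365T in LIF differed from WT in 1968 genes, 1140 higher and 828 lower. The highest rises were those of Egr1, an immediate early transcription factor (3.69 ± 1.08), the X-linked genes Sh3bgrl (3.44 ± 0.24), Scml2, a Polycomb group gene (3.21 ± 0.30), and Nxf3 (3.15 ± 0.25), and the oocyte gene Nlrp4c (2.93 ± 0.35). Scml2 went from 230 ± 99.5 to 2064 ± 103 normalised counts (SD, n = 2; adjusted p = 6.4e-05). Among the largest falls were those of Clca3b (-3.72 ± 0.38), Arhgef38 (-3.29 ± 0.39), Peg3 (-2.50 ± 0.25) and Gad1, a gene of GABA synthesis (-2.36 ± 0.38). Germline genes were higher in 11 of 19 cases and lower in 0 (13 and 1 over the list alone). Brdt, a testis bromodomain gene (2.54 ± 0.31), Rhox2a (2.39 ± 0.41) and Tex11 (1.51 ± 0.29) were among them, and Asz1 went from 1 recovered read to 105, a ratio of 123 (21.7 to 4923). The germline list was past the threshold with the preset correlation and by fry (adjusted p = 1.78e-06 and 0.0275), with adjusted p = 0.486 with an estimated correlation. Imprinted genes had 3 of 29 higher and 9 lower (4 and 9 over the list alone), with Peg3, Nnat (-1.96) and Mirg (-1.84) lower and Peg10 (1.81) higher. The imprinted list's median of -0.10 turned to 0.03 with TPM. Of 18 MEK and ERK targets 3 were higher and 3 lower, the same over the list alone: Egr1 and Egr3 (2.18) were higher, Dusp6 (-1.69) and the ETS factor gene Etv1 (-1.61) lower, and the list's median of 0.05 and mean of 0.21 differ in sign from its camera test. This median had no stable direction: it was -0.14 with a mean of at least 50, and from -0.23 to 0.28 without 1 library.

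Of the genes higher in K365T in LIF 282 lay on chromosome 1, 276 on chromosome 11 and 59 on distal chromosome 17. Without 1 library the count was 734 (WT replicate 1), 736 (K365T replicate 2), 759 (WT replicate 2) or 1005 (K365T replicate 1), and the calls of Egr1, Egr3, Nnat, Mirg, Peg10 and Tex11 ended in at least 1 of these fits. Without WT replicate 2 the adjusted p of Egr1 was 0.392. It was not called by edgeR (adjusted p = 0.139) or DESeq2 (adjusted p = 0.154), and with TPM, where the median difference of all genes was 0.11 against -0.02, 78.4% of 1382 calls were higher against 57.9% with the normalised counts. With the LIF libraries alone the count was 2936.

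Q418R in LIF differed from WT in 754 genes, 331 higher and 423 lower. Epdr1 (3.22 ± 0.31), Cpe, which encodes carboxypeptidase E (3.05 ± 0.30), Igsf10 (2.60 ± 0.43), Nlrp4c (2.41 ± 0.35) and Brdt (2.31 ± 0.31) were the highest. Cpe went from 51.5 ± 3.51 to 470 ± 155 normalised counts (SD, n = 2; adjusted p = 0.000154). Among the largest falls were those of Peg3 (-2.32 ± 0.25), Antxr1 on chromosome 6 (-2.27 ± 0.28), Arhgef38 (-2.03 ± 0.39) and Tspoap1 (-1.91 ± 0.27). Of 19 germline genes 3 were higher and 0 lower (9 and 1 over the list alone), Brdt, Tex101 (2.02 ± 0.28) and Rhox2a (1.76 ± 0.41), with adjusted p = 0.551 with an estimated correlation against 1.89e-05 with the preset one. Of the 423 lower genes 134 lay on chromosome 6, and of the 331 higher genes 62 on distal chromosome 17. Without 1 library the count was 156 (Q418R replicate 1), 157 (WT replicate 1), 225 (WT replicate 2) or 246 (Q418R replicate 2), and the calls of Igsf10, Arhgef38 and Rhox2a ended in at least 1 fit. The count was 254 with TPM, where 68.1% were higher, 1183 by DESeq2 and 1278 with the LIF libraries alone.

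Without LIF, R342C again differed from WT in few genes, 66 higher and 19 lower. Cubn, which encodes the endocytic receptor cubilin of visceral endoderm, rose by 3.70 ± 0.49, from 45.4 ± 16.8 to 638 ± 230 normalised counts (SD, n = 2; adjusted p = 0.00173). The nuclear receptor gene Nr5a2 (1.33 ± 0.25) was higher, as were Kcng3 (1.53 ± 0.29), Ltbp1 (1.36 ± 0.27) and Ston1 (1.29 ± 0.17) on distal chromosome 17. Peg3 (-2.69 ± 0.25) was lower, as were the X-linked Xlr3c (-3.10 ± 0.37), Xlr4a (-3.08 ± 0.56) and Xlr3a (-2.58 ± 0.42), of the family named above, and Zfy1 on the Y chromosome (-2.37 ± 0.47). Of the 66 higher genes 56 lay on distal chromosome 17. Of 29 imprinted genes Peg3 and H19 (-2.38 ± 0.41) were lower and 0 higher (3 and 0 over the list alone), and the list's median of 0.07 and mean of -0.14 differ in sign. The count of 85 was 32 without R342C replicate 2 and 52 without WT replicate 2, and Kcng3, Ltbp1, Nr5a2, Xlr4a, Xlr3a, Zfy1 and H19 lost their calls in both of these fits. It was 10 with the libraries without LIF alone, 19 outside the shifted windows, 42.1% of them higher, and 139 by DESeq2. The genes outside again included those of chromosome 17 from 90 Mb, with a median difference of 1.03.

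K365T without LIF differed from WT in 2613 genes, 1311 higher and 1302 lower, more than in LIF, but with the libraries of each medium fitted alone the order turned, with 573 without LIF against 2936 in LIF. Among the rises were the early germline and naive state gene Dppa3 (3.69 ± 0.55), the histone gene H3f4 (3.56 ± 0.26), the Wnt ligand gene Wnt8a (3.28 ± 0.88), the channel gene Trpa1 (3.12 ± 0.36) and the receptor gene Flt1 (2.99 ± 0.67). H3f4, whose name had no position in the annotation, went from 104 ± 9.54 to 1288 ± 275 normalised counts (SD, n = 2; adjusted p = 1.52e-05). Tspo2 (-3.36 ± 0.73), Peg3 (-2.90 ± 0.25), the calcium-binding protein gene S100a1 (-2.75 ± 0.66), Magea4 (-2.66 ± 0.42) and Clca3b (-2.59 ± 0.38) were the largest falls. Of the naive genes 6 of 18 were higher and 0 lower (8 and 4 over the list alone), with Dppa3, Nr5a2 (2.81 ± 0.25), the metabolic enzyme gene Tdh (2.72 ± 0.29) and Klf2 (2.00 ± 0.38). The naive list's median difference was 0.70, and -0.16 without K365T replicate 1. Of Wnt targets 4 of 14 were higher and 0 lower (8 and 0 over the list alone): Sp5 (2.38 ± 0.72), Cdx1 (1.98 ± 0.57), Axin2 (1.36 ± 0.27) and Znrf3 (0.75 ± 0.14). Of p53 targets 6 of 18 were higher and 0 lower (10 and 0 over the list alone), among them Btg2 (1.35 ± 0.21), Phlda3 (1.32 ± 0.20), Ccng1 (1.17 ± 0.17) and the cell cycle inhibitor gene Cdkn1a (1.04 ± 0.15).

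In the same comparison 6 of 18 unfolded protein and amino acid stress genes were lower and 0 higher (8 and 0 over the list alone), with the cystine transporter gene Slc7a11 (-1.90 ± 0.41), Trib3 (-1.57 ± 0.48), Chac1 (from 915 ± 383 to 319 ± 129 normalised counts) and the transcription factor gene Atf4 (-1.15 ± 0.23). Of protocadherin gamma genes 9 of 14 were higher and 0 lower, the same over the list alone, including Pcdhgb5 (2.31 ± 0.45), Pcdhga8 (1.94 ± 0.48), Pcdhgb4 (1.90 ± 0.48) and Pcdhga2 (1.70 ± 0.33), at levels of 11.4 to 15.3 normalised counts over the 16 libraries. Hox genes had 7 of 28 higher and 0 lower (9 and 0 over the list alone), with Hoxb1 (2.34 ± 0.64), Hoxa3 (2.16 ± 0.35) and Hoxc4 (2.06 ± 0.36), while Hoxb13 had 19 recovered reads against 1 in WT (20.1 times, 3.20 to 837). Of 9 genes of the 2-cell-like state 4 were higher and 0 lower (6 and 0 over the list alone): Arg2 (1.68 ± 0.40), Sp110 (1.56 ± 0.37), Zscan4f (1.46 ± 0.38) and Zscan4e (1.20 ± 0.33). For the naive, Wnt, p53, stress, protocadherin gamma, Hox and 2-cell lists the preset-correlation calls were lost, with adjusted p between 0.395 and 0.702 with an estimated correlation.

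For K365T without LIF 304 of the higher genes lay on chromosome 1, which holds Nr5a2 and Trpa1, 349 on chromosome 11 and 56 on distal chromosome 17. The list counts of K365T in both media were not split by chromosome. Those without LIF include genes of these raised chromosomes, such as Nr5a2 of the naive list. A list count can therefore not be read apart from the chromosome shifts. The same holds for the balance of calls, with 599 higher and 687 lower outside the shifted windows, recentred. The count was 865 without WT replicate 2, 1230 without K365T replicate 2 and 1286 outside the shifted windows, and the share of higher calls was 75.7% with TPM and 64.1% with upper-quartile scaling against 50.2%. Of the 37 genes named for it 20 lost their call in at least 1 fit without 1 library, 18 without K365T replicate 2 (Wnt8a, Flt1, Tspo2, S100a1, Arg2, Sp110, Zscan4f, Zscan4e, Sp5, Cdx1, Axin2, Pcdhga8, Pcdhgb4, Hoxb1, Slc7a11, Trib3, Chac1 and Atf4), 16 without WT replicate 2, where Pcdhgb5 is added, and Hoxb13 without K365T replicate 1, with adjusted p up to 0.331.

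Q418R without LIF differed from WT in 1092 genes, 537 higher and 555 lower. Cubn was the highest (3.71 ± 0.49), from 45.4 ± 16.8 to 695 ± 440 normalised counts (SD, n = 2; adjusted p = 0.00103), followed by Cpe (3.08 ± 0.30), Dppa3 (2.89 ± 0.55), the zinc finger gene Zbtb39 (2.74 ± 0.19) and the semaphorin gene Sema6a (2.65 ± 0.66). The largest falls were those of Tspo2 (-3.47 ± 0.73), Lrrc31 (-2.91 ± 0.69), H2-K2, of the MHC class I family with its close paralogs (-2.50 ± 0.57), S100a13 (-2.44 ± 0.59) and Arrdc2 (-2.36 ± 0.43). Of endoderm genes 4 of 15 were higher and 0 lower (4 and 1 over the list alone): Cubn and the transcription factor genes Gata6 (1.94 ± 0.35) and Sox17 (1.66 ± 0.35), with the laminin gene Lama1 (1.23 ± 0.23). Of naive genes Dppa3, Nr5a2 (2.24 ± 0.25), Tdh (2.09 ± 0.29) and Klf2 (1.64 ± 0.38) were higher, 4 of 18 with 0 lower (4 and 2 over the list alone), while of formative and primed genes 4 of 18 were higher and 0 lower (5 and 0 over the list alone), Cdh2 (1.82 ± 0.43), Otx2 (1.67 ± 0.31), Sox3 (1.07 ± 0.29) and Sox4 (0.98 ± 0.24). The 2-cell-like state had 5 of 9 higher and 0 lower (8 and 0 over the list alone), including Zscan4f (2.14 ± 0.38), Sp110 (1.79 ± 0.37), Zscan4c (1.78 ± 0.42) and Arg2 (1.76 ± 0.40), and protocadherin gamma 4 of 14 higher and 0 lower (6 and 0 over the list alone), Pcdhga1 (2.77 ± 0.39), Pcdhga3 (2.53 ± 0.51), Pcdhga2 (2.43 ± 0.33) and Pcdhgb4 (1.94 ± 0.48). For the lists called with the preset correlation, endoderm, formative, 2-cell and protocadherin gamma, adjusted p lay between 0.395 and 0.866 with an estimated correlation. The median of the formative list had no stable direction: it was -0.084 without WT replicate 2 and 0.52 without WT replicate 1.

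Of the genes lower in Q418R without LIF 157 lay on chromosome 6, and of those higher 64 on distal chromosome 17. The count was 248 without WT replicate 2, 273 without Q418R replicate 1, 702 without Q418R replicate 2, 65 with the libraries without LIF alone, 567 outside the shifted windows and 1658 by DESeq2. The share of higher calls was 77.0% of 610 with TPM, and upper-quartile scaling gave 672 higher and 448 lower, against 49.2%. Of the 28 genes named 21 lost their call in at least 1 fit without 1 library, with adjusted p up to 0.277; Cubn, Cpe, Zbtb39, Nr5a2, Tdh, Pcdhga1 and Pcdhga2 were called in each of the 4.

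**Figure D2:**
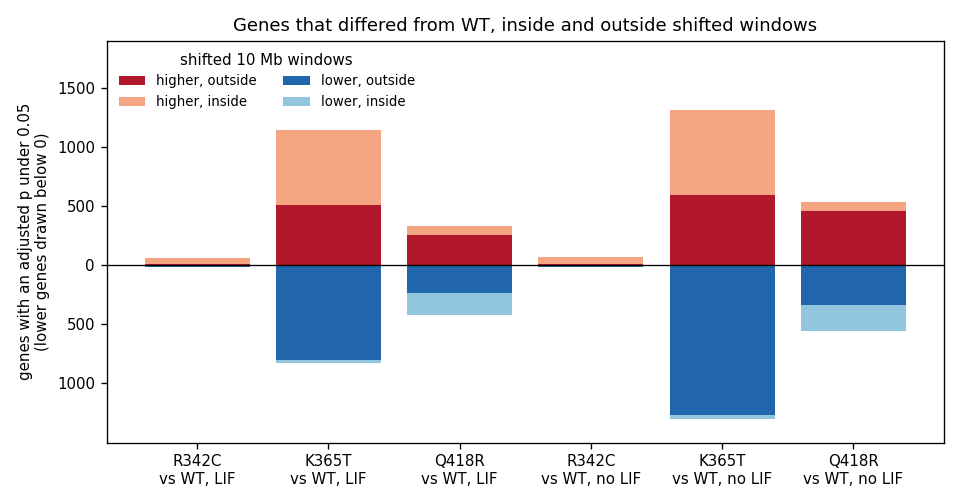
Number of genes that differed from WT at an adjusted p under 0.05 (vertical axis, lower genes drawn below 0) in each of the 6 comparisons of a mutant line with WT, with pale bars for genes inside windows whose median was shifted and dark bars for the other genes. Of the calls 46 of 74 (R342C), 657 of 1968 (K365T) and 256 of 754 (Q418R) in LIF lay inside such windows. The rule did not call chromosome 17 from 90 Mb, most of chromosome 8 in K365T or chromosome 1 in Q418R, which count among the other genes.

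The response to the medium itself differed between K365T and WT in 117 genes, 59 with a positive and 58 with a negative difference. Trh, which encodes thyrotropin-releasing hormone, fell in WT (-1.28 ± 0.49) and rose in K365T (2.87 ± 0.49), a difference of 4.15 ± 0.70. Its recovered reads also rose in the other mutants, from 3409 to 5100 in R342C and from 2395 to 4589 in Q418R. The difference in Trh thus need not be particular to K365T. Ephx2, an epoxide hydrolase gene, fell in WT (-1.49) and rose in K365T (1.84), Tdh fell less in K365T (-1.95) than in WT (-4.82), and Crxos fell by 6.84 in K365T and to 2 recovered reads in WT. Tnfrsf19 fell in WT (-2.22), with a value of 0.84 in K365T that did not pass. Sh3bgrl rose less in K365T (1.31) than in WT (4.12). Rhox5 (2.64), Ank (1.66) and Cdkn2a (1.33) rose in WT; in K365T Cdkn2a fell (-0.93), and Rhox5 (0.28) and Ank (-0.60) did not pass. Cobll1 fell in K365T (-2.25), with 0.36 in WT that did not pass. The adjusted p of these 10 differences lay between 0.000479 and 0.0466. The count was 11 without WT LIF replicate 1, 27 without K365T LIF replicate 2, 31 without WT no LIF replicate 2, 40 without WT LIF replicate 2 and 259 without K365T no LIF replicate 1, and Ephx2, Sh3bgrl and Cobll1 kept their call without each library in turn. It was 22 without a filter, 28 with TPM, 447 by DESeq2 and 477 with a replicate block within each line.

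Q418R differed from WT in its response in 25 genes, 16 with a positive and 9 with a negative difference. Otx2, a factor of the formative state, rose by 5.42 ± 0.31 in Q418R and by 2.31 ± 0.31 in WT, and Cubn by 6.55 and 2.71. The recovered reads of Cubn rose from 5 to 1293 in Q418R and from 4 to 1306 in R342C. Its larger rise thus need not be particular to Q418R. Nr5a2 fell by 2.99 in Q418R and by 5.24 in WT, and the neurotrophin receptor gene Ntrk3 (-3.59 and -6.48) also fell less in Q418R, while the hyaluronan-binding gene Cemip fell by 3.14 in Q418R and to 3 recovered reads in WT. The glutamate transporter gene Slc1a3 (1.97 and 3.93), the protease gene Mmp2 (3.12 and 4.92) and the tight junction gene Cgn (2.18 and 3.45) rose less in Q418R than in WT. Fam111a (1.58) and Gstp1 (1.61) rose in WT, with 0.10 and 0.32 in Q418R that did not pass. The adjusted p of these 10 differences lay between 0.0394 and 0.0488, and each of the 10 lost its call without at least 1 library. The count was 0 without Q418R LIF replicate 1 or 2, Q418R no LIF replicate 1, WT LIF replicate 2 or WT no LIF replicate 2, 1 without WT LIF replicate 1, 6 without Q418R no LIF replicate 2 and 51 without WT no LIF replicate 1; it was also 0 without a filter, where 2868 genes had an unadjusted p under 0.05, and 0 with TPM, where 1215 had, against 20 by edgeR, 162 by DESeq2, 8 with a replicate block and 151 with a replicate block within each line. For R342C 0 genes were called by limma, with 288 at an unadjusted p under 0.05, 0 by edgeR, with 311, and 2 by DESeq2. On simulated data 58% of 4-fold and 12% of 2-fold differences of this kind were found.

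**Figure D3:**
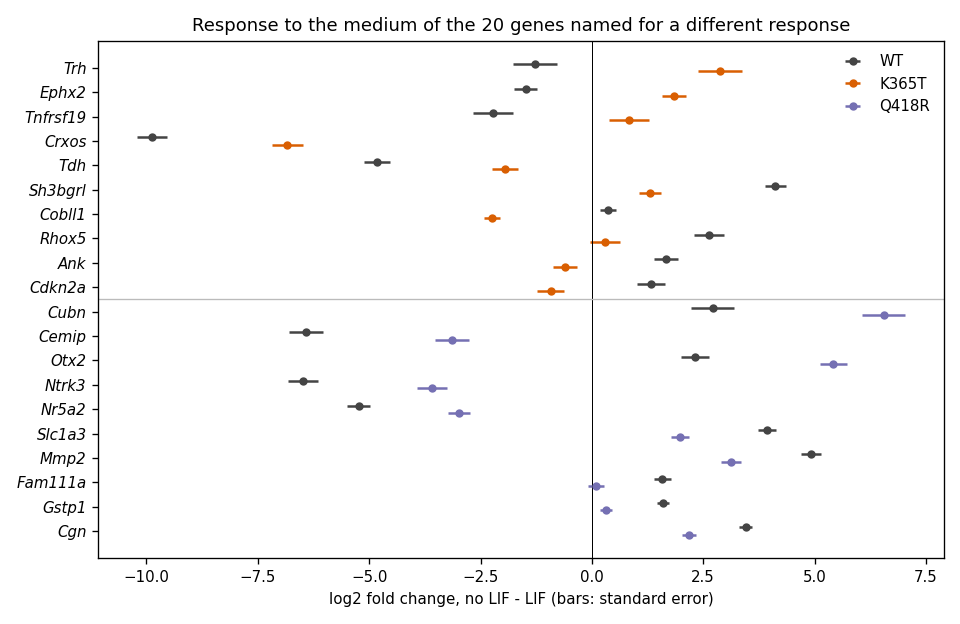
Log2 fold change between media (horizontal axis, no LIF minus LIF) of the 20 genes named for a response that differed from WT, with WT in grey, K365T in orange (upper 10 genes) and Q418R in purple (lower 10), and bars for the standard error. Trh and Ephx2 lie below 0 in WT and above 0 in K365T, while the 2 responses of each Q418R gene lie on the same side. The WT values of Crxos and Cemip are compressed by the added 4.

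The mutant lines also differed from one another, in 1956 genes in LIF and 1625 without LIF by the F test. In LIF the 3 smallest p belonged to X-linked genes: Sh3bgrl had 50.4 ± 8.99 normalised counts in R342C, 499 ± 83.3 in K365T and 141 ± 46.3 in Q418R (SD, n = 2), Nxf3 had 58.3 ± 15.4, 634 ± 15.9 and 233 ± 13.4, and Scml2 had 144 ± 36.0, 2064 ± 103 and 520 ± 46.7. Ephx2 (1084, 376 and 3389) and Gad1 (91.1, 28.9 and 697) were highest in Q418R. Without LIF Zbtb39 had 106 ± 6.82, 90.4 ± 22.1 and 803 ± 53.3, the kinase gene Camk1d 731 ± 26.1, 195 ± 1.54 and 480 ± 50.5, the dynein gene Dnah8 3227 ± 150, 7136 ± 25.7 and 3546 ± 408, Septin1 654, 123 and 226, and Mcf2 197, 506 and 558. The adjusted p of these 10 genes was at most 0.00019. Leaving out 1 library gave 842 (R342C replicate 2), 1004 (R342C replicate 1), 1023 and 1102 (K365T replicates 1 and 2) and 1174 and 1207 (Q418R replicates 1 and 2) in LIF, and 695, 807 and 1068 without R342C replicate 2, R342C replicate 1 and Q418R replicate 2 in the other medium. With TPM the counts were 1044 and 597, and with the libraries of 1 medium alone 3092 and 56.

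Calls against WT recurred between mutants, whose comparisons in a medium share the same 2 WT libraries. In LIF K365T and Q418R shared 183 higher and 127 lower genes, and without LIF 290 and 312. R342C shared 51 higher genes with K365T and 55 with Q418R in LIF, and 58 and 63 without LIF. Across genes the differences correlated at r = 0.37, 0.38 and 0.54 in LIF (R342C with K365T, R342C with Q418R, K365T with Q418R) and at 0.46, 0.56 and 0.67 without LIF, where the shared WT libraries alone, with each group at its own spread, gave 0.45 to 0.57 in simulations. K365T with Q418R lay above the highest simulated value in both media (0.47 in LIF and 0.52 without LIF). The other 4 values lay below theirs. With 1 spread for all groups, where the highest simulated value was 0.52, R342C with Q418R without LIF lay above it as well. A low r cannot decide on sharing, since changes of 1 line alone lower it and the simulations hold none. The covariance of each pair lay above its highest simulated value, from 0.0556 against 0.0386 (R342C with Q418R in LIF) to 0.194 against 0.0652 (K365T with Q418R without LIF). With a different WT library for each mutant the covariance of K365T and Q418R was 0.0966 in LIF and 0.132 without LIF, above the variance between WT replicates (0.0730 and 0.123). For the pairs with R342C it was 0.0194 to 0.0355, below that variance but above the highest of the simulations, 0.00222 to 0.00404. In these simulations genes vary independently, so that common changes of R342C and the others stay open apart from distal chromosome 17. This covariance also holds any difference of the WT line itself, which is common to all comparisons with WT. Of the genes higher in all 3 mutants, 44 of 49 in LIF and 51 of 56 without LIF lay on chromosome 17 from 70 Mb. In both media the same 48 genes were higher and 8 lower in R342C, 522 and 286 in K365T, and 131 and 155 in Q418R. In all 3 mutants and both media 46 genes differed in the same direction, 41 of them higher genes of distal chromosome 17. The other 5 were Peg3, N4bp2l2 and Gm47647, which were lower, and Tex15 and Gm6969, which were higher. Peg3 had 4766 ± 2593 normalised counts over the 4 WT libraries and 852 ± 535 over the 12 mutant libraries (SD), N4bp2l2, a gene on chromosome 5, 3547 ± 125 and 2289 ± 193, and Tex15, a germline gene on chromosome 8, 700 ± 145 and 1658 ± 368. The 7 genes of chromosome 5 from 150 Mb, where N4bp2l2 lies, had a median difference of -0.54 in R342C and -0.41 in K365T. The fall of N4bp2l2 may thus not be particular to this gene. These 5 were singled out after their values were seen, and the 2 WT libraries of a medium cannot be split among all 3 mutants.

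Differences from WT also followed chromosome position. On chromosome 17 all 68 genes with a mean of at least 100 from Clip4 (start 71768473) to the last gene (end 94878321) were higher in the mutants, with a mean log2 difference over the 3 mutants and both media of 0.92 ± 0.21 (SD), or 1.91-fold. The 29 genes from 60 Mb to Wdr43 (end 71659031) had a mean of 0.02 ± 0.17. The DNA repair gene Msh6, the signalling gene Sos1 and Birc6, an inhibitor of apoptosis, lie in this segment. Relative to its own mean over libraries the segment lay between -0.74 and -0.70 in the 4 WT libraries and between 0.12 and 0.30 in the 12 mutant libraries. In K365T the median difference was 0.48 in LIF and 0.44 without LIF on chromosome 1, 0.35 and 0.36 on chromosome 11, and 0.21 and 0.18 on chromosome 8. In Q418R it was -0.41 and -0.42 on chromosome 6, -0.51 in both media on chromosome 5 from 20 to 40 Mb, and 0.17 in both media on chromosome 1, where the 4 Q418R libraries lay between -0.02 and 0.07 and the 4 WT libraries between -0.19 and -0.16 relative to the mean over libraries. On chromosome 3 from 140 to 160 Mb the medians of all 3 mutants were between 0.25 and 0.48. Windows called shifted by the rule held 0.997% of tested genes and 46 of 74 calls in LIF and 54 of 85 without LIF for R342C, 14.8% of genes with 657 of 1968 and 755 of 2613 calls for K365T, and 6.91% of genes with 256 of 754 and 300 of 1092 calls for Q418R. Of the interaction calls 23 of 117 in K365T and 0 of 25 in Q418R lay inside. The rule called only 40 to 60 Mb of chromosome 8 in K365T. It did not call chromosome 1 in Q418R, or chromosome 17 from 90 Mb, which has too few genes, in any mutant. With genes outside the windows alone, recentred, 16 and 19 genes differed in R342C, 935 and 1286 in K365T and 280 and 567 in Q418R. In K365T these were 511 higher and 424 lower in LIF, and 599 and 687 without LIF. In the main fit the genes outside the K365T windows had 512 higher and 799 lower in LIF, and 590 and 1268 without LIF. On every chromosome but 1, 8 and 11 the K365T median lay below 0 in both media (-0.14 and -0.16 on chromosome 7). The recentred fit left out windows called in any mutant, and it kept the rest of chromosome 8 and chromosome 17 from 90 Mb. The removal of genes and the recentring were not run apart.

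**Figure D4:**
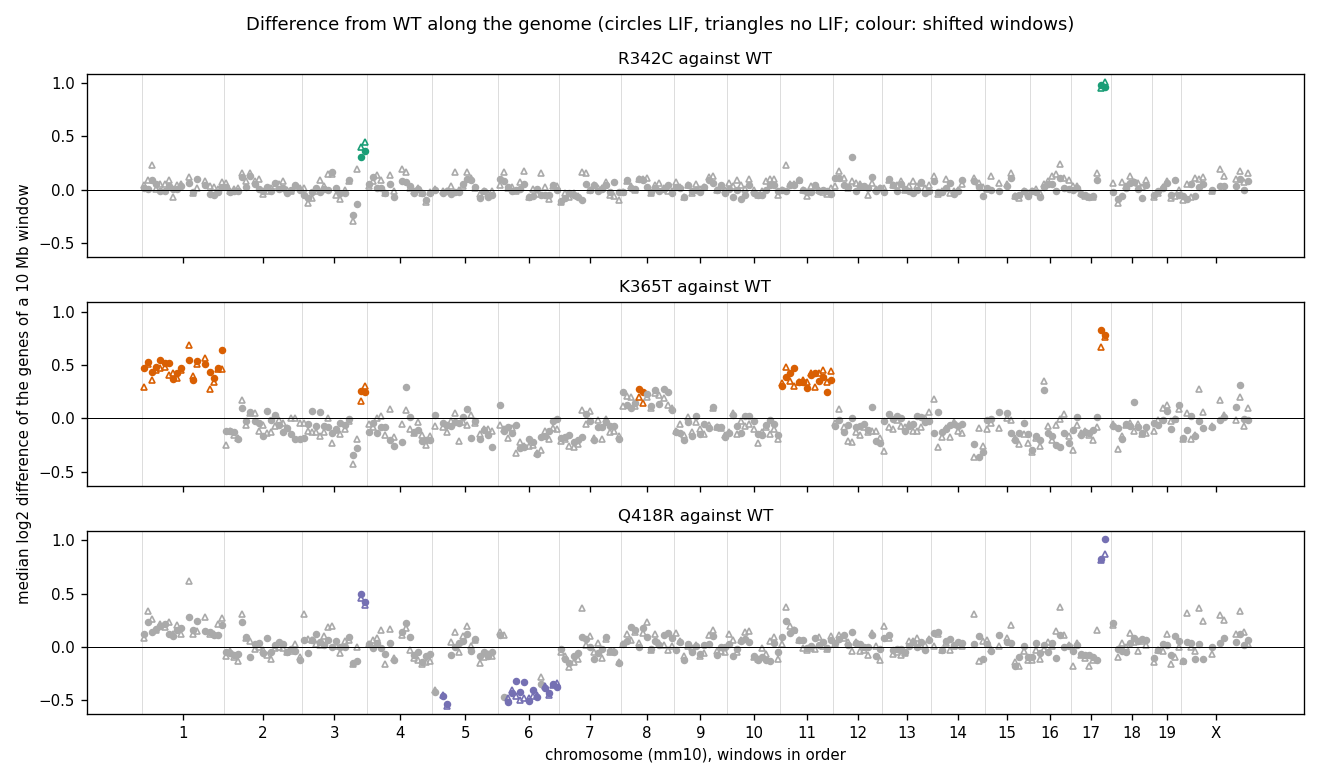
Median log2 difference from WT (vertical axis) of the genes of each 10 Mb window along the genome (horizontal axis, chromosomes in order) for each mutant line, with circles for LIF, triangles for no LIF and colour for shifted windows. Distal chromosome 17 is raised in all 3 lines, chromosomes 1 and 11 in K365T, and chromosome 6 is lowered in Q418R.

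**Figure D5:**
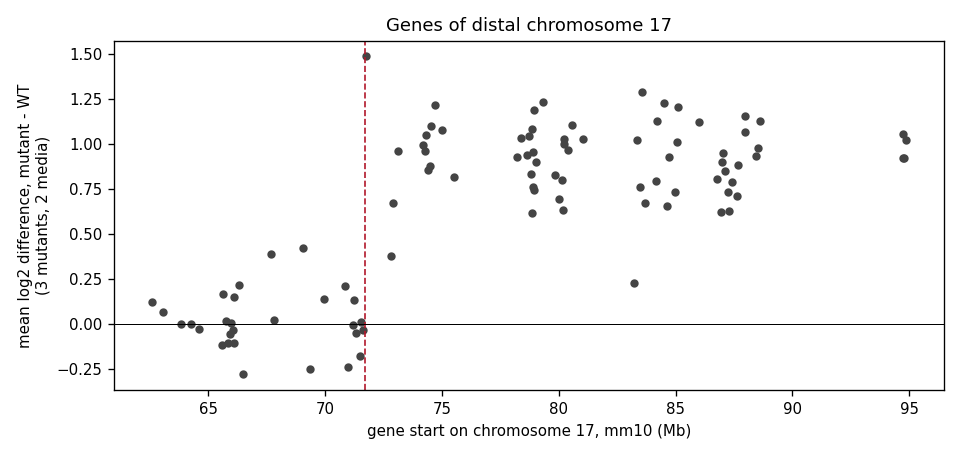
Mean log2 difference of the mutants from WT (vertical axis, 3 mutants and 2 media) for each gene of distal chromosome 17 with a mean of at least 100, by gene start (horizontal axis, Mb, mm10). The dashed line marks the edge between Wdr43 and Clip4, with a mean of 0.02 before it and 0.92 after it.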

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

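The tests of distal chromosome 17, the test of scaling on whole chromosomes, the count of lines per mutation and the tests of the naive genes without 1 library were chosen only after the result was seen. The response to the medium differed between K365T and WT in 117 genes and between Q418R and WT in 25 genes by a test of the difference itself.

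In K365T the difference in response was positive for the hormone gene Trh (4.15), Ephx2 (3.33), Tnfrsf19 (3.06), Crxos (3.03) and Tdh (2.87), and negative for Sh3bgrl (-2.81), Cobll1 (-2.61), the homeobox gene Rhox5 (-2.36), Ank (-2.27) and the cell cycle inhibitor gene Cdkn2a (-2.26). In Q418R it was positive for Cubn (3.84), Cemip (3.27), Otx2 (3.11), Ntrk3 (2.89) and Nr5a2 (2.25), and negative for Slc1a3 (-1.96), Mmp2 (-1.81), Fam111a (-1.49), Gstp1 (-1.28) and Cgn (-1.27). The values of Crxos and Cemip, which had at most 3 recovered reads in WT without LIF, are compressed by the added 4. By recovered reads Trh also rose in R342C (3409 to 5100) and Q418R (2395 to 4589), and Cubn in R342C (4 to 1306). Of the K365T genes Ephx2, Sh3bgrl and Cobll1 kept their call without each of the 8 libraries in turn. Of the Q418R genes 0 of 10 did: all 10 lost it without Q418R LIF replicate 1, where the highest adjusted p was 0.237 (Cubn).

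Genes of distal chromosome 17 were higher in all 3 mutant lines than in WT. The tests used the genes with a mean of 10 to 100, which had no part in finding the edge. Gene by gene control by CTCF would leave some genes unchanged or lower, and 100% of the 17 such genes after the edge lay above 0, against 56.2% on other chromosomes. The scaling of the deposited table would move the genes before the edge as well, and the mean of 15 such genes was 0.074. A copy number difference between the WT line and the mutant lines may underlie the pattern: 88.2% of the 17 genes were over 0.5, and their median of 0.95 lies near the log2 ratio of 1 for 2 copies against 1. DNA was not measured, so that a lower copy number in WT stays a hypothesis. Control of the whole segment by CTCF, common to the 3 mutants, cannot be told apart from it by these values.

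Chromosomes 1 and 11 were higher in K365T and chromosome 6 was lower in Q418R. Chromosome 1 was also higher in Q418R, by less (0.17 in both media). Genes with a mean of 10 to 100, which had no part in finding the pattern, moved with the others, with medians relative to the other chromosomes of 0.44 (chromosome 1), 0.28 (chromosome 11) and -0.32 (chromosome 6), and a weaker 0.16 on chromosome 8 in K365T, with 66.5% of genes on the same side. The scaling of the deposited table, 1 factor per library, would move all chromosomes alike, but the smallest of these 4 gaps was 0.16. A copy number difference between lines, in part of the cells or in all, could account for these shifts, where 3 copies against 2 give 0.58 and 1 against 2 gives -1. The fall of chromosome 6 in Q418R (-0.41 in LIF and -0.42 without LIF) was well short of -1. In size it was nearer to the 0.58 of 3 copies against 2. Chromosome-wide control by the mutant CTCF cannot be told apart from a copy number difference, since there is 1 line per mutation.

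Naive pluripotency genes were higher in K365T without LIF. The median of all members rested on 1 library apart from its replicate, as it was -0.16 without K365T replicate 1. This does not cover Nr5a2, Tdh, Dppa3 and Klf2, whose highest adjusted p without that library was 0.0194. Cells that kept the LIF state, mixed into replicate 1, would bring all abundant transcripts of that state in a like share, but the lowest level left was 0% and 20 of 78 such genes had under 0.1 of the naive median left. A slower exit from the naive state in the culture of replicate 1 may remain for the other members, and for the 4 genes an effect of K365T or of its line stays open. It need not be particular to K365T: the same 4 genes were higher in Q418R without LIF, and Nr5a2 in R342C too (1.33), against the same 2 WT libraries, so that a low level in these WT libraries or in the WT line stays open as well. The calls of Dppa3 and Klf2 in Q418R and of Nr5a2 in R342C depended on single libraries.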

How the results depend on the processing

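The fit outside the shifted windows and the replicate block within each line were chosen only after the data were seen. Of the values recomputed under alternatives other than leaving out a library, 152 counts stayed within 1.5 times and 36 moved further. For single genes 2754 values kept their direction and side of the threshold, 187 were no longer past it and 5 reversed, and for lists 315 kept both, 41 passed a threshold that they had missed and 7 reversed. The responses to the medium in the 4 lines stayed within 1.5 times under each alternative run. Except where the setting itself shows it, the cause was not tested.

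With the genes outside the shifted windows alone, recentred, the counts against WT were 16 (R342C), 935 (K365T) and 280 (Q418R) in LIF, 19, 1286 and 567 without LIF, and 959 and 674 among the mutants. Dropped genes do not account for all of this: of the 1197 main calls of K365T in LIF that were still tested 893 were called, and of the 27 of R342C 16. With the libraries of 1 medium alone, which changes both the number of samples and the spread that is shared, the counts were 2936 (K365T) and 1278 (Q418R) in LIF, 10, 573 and 65 (R342C, K365T and Q418R) without LIF, and 3092 and 56 among the mutants. DESeq2 gave 149 and 1183 (R342C and Q418R) in LIF, 139 and 1658 without LIF, 2642 among the mutants without LIF, and 2, 447 and 162 differences in response (R342C, K365T and Q418R). On simulated data DESeq2 called more unchanged genes than limma, 17 against 3 for the K365T interaction, and recovered more 2-fold differences, 32% against 12%. TPM gave 254 (Q418R in LIF), 610 (Q418R without LIF), 1044 and 597 among the mutants, and 28 (K365T) and 0 (Q418R, 1215 at an unadjusted p under 0.05) differences in response. For these differences no filter gave 22 and 0 (2868 at an unadjusted p under 0.05), a replicate block within each line 477 and 151, and in Q418R upper-quartile scaling 9 and a replicate block 8. Of the 273 list tests 86 passed with the preset correlation and 60 by fry, against 0.

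Leaving out 1 library leaves an arm with 1 sample, assumed to vary like the other groups. The responses then ranged from 6925 to 7897 genes in WT, 6504 to 7072 in R342C, 6270 to 7176 in K365T and 6557 to 7122 in Q418R. Against WT in LIF the ranges were 30 to 48 (R342C), 734 to 1005 (K365T) and 156 to 246 (Q418R), and without LIF 32 to 85, 865 to 2724 and 248 to 1580. The differences in response ranged from 0 to 1 (R342C), 11 to 259 (K365T) and 0 to 51 (Q418R), and the F tests from 842 to 1207 in LIF and 695 to 1463 without LIF. Of single genes 975 values kept direction and side, 267 were no longer past the threshold and 6 reversed.

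The values that reversed had no call by limma, or for lists by camera with an estimated correlation. T in WT was 0.0011 with upper-quartile scaling, 0.019 by edgeR, 0.036 by DESeq2 and ranged from -0.57 to 0.45 without 1 library (the latter WT no LIF replicate 1). Ctcf with TPM was 0.033 in the Q418R response and 0.12 in R342C in LIF, and without 1 library it ranged from -0.33 to 0.097 in the Q418R response (the latter Q418R no LIF replicate 2), with 0.015 and 0.11 in R342C in LIF (R342C replicate 2, WT replicate 1), and -0.040 and -0.10 without LIF (R342C replicate 2, WT replicate 2), where the highest was 0.13. Medians of lists in the WT response were 0.0011 with upper-quartile scaling and from -0.000603 to 0.24 without 1 library for primitive streak (the latter without WT no LIF replicate 1, 0.22 without WT LIF replicate 2, 0.12 without WT no LIF replicate 2), 0.026 with TPM, 0.061 with upper-quartile scaling and 0.078 and 0.092 without WT LIF or no LIF replicate 1 for proliferation, 0.11 for Wnt targets and 0.10 for stress without WT no LIF replicate 1, and 0.0056 for p53 targets without WT LIF replicate 2. The lowest medians without 1 library were -0.063 for proliferation, -0.43 for Wnt targets, -0.41 for stress and -0.18 for p53 targets. Against WT, imprinted genes were at 0.075 (R342C in LIF) and 0.033 (K365T in LIF) with TPM, and in R342C without LIF at -0.018 with a mean of at least 50, -0.0045 without R342C replicate 2 and -0.034 without WT replicate 2. MEK and ERK targets in K365T in LIF were at -0.14 with a mean of at least 50, -0.23 without K365T replicate 2 and -0.15 without WT replicate 2, with 0.28 as the highest. Without LIF, naive genes were at -0.16 in K365T without replicate 1 and at -0.0023 in Q418R without replicate 1, and formative genes in Q418R at -0.084 without WT replicate 2. The highest medians of these 3 without 1 library were 1.42, 0.26 and 0.52.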

Other observations

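The test of the mitochondrial share was chosen only after the values were seen. Messenger RNAs of the mitochondrial genome, which encode parts of the respiratory chain, took a smaller share of normalised counts in the WT line than in the mutant lines. The share was 1.26% to 1.69% in the WT libraries (mean 1.52%, SD 0.204, n = 4) and 1.85% to 2.71% in the mutant libraries (mean 2.27%, SD 0.282, n = 12). In an exact two-sided permutation test within each medium (784 splits) p was 0.00128, the smallest that these splits can give. As the ranges had been seen not to overlap, p could take only this value, and it adds no evidence. The mutant libraries come from 3 lines and the WT libraries from 1, so that the test compares libraries, not independent lines. Structural RNAs, which include the mitochondrial ribosomal RNA mt-Rnr1, took their largest share, 7.28%, in a WT library as well. The share of mt-Rnr1 was 0.68% to 1.23% in the WT libraries and 0.24% to 0.87% in the mutant libraries, so that it was not lower in WT. Ribosomal RNA was depleted before sequencing, and these shares do not measure total mitochondrial RNA.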
